A study of Mus musculus with 10 samples.

How the data were processed

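Single-cell RNA sequencing was done on kidneys of C57BL/6 mice after ischemia-reperfusion (IR), an injury in which blood flow is stopped and then restored. The labels give 10 libraries: 2 Sham libraries (A and B), 1 library each at 4 hours (IR H4), 12 hours (IR H12), 1 day (IR D1), 14 days (IR D14) and 28 days (IR D28), and 3 libraries (A, B and C) at 5 days (IR D5). Per the labels' protocols, both kidneys were minced, digested with enzymes and strained, red cells were lysed, and single cells were barcoded in droplets with a chemistry that reads the starts of transcripts. Nothing in the labels says whether the libraries of a group come from separate animals, so p-values measure only the spread between these samples, which may be technical.

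The authors deposited, for every library, a sparse matrix of raw UMI counts per gene and barcode. Per the submitters' processing notes the tool was Cell Ranger and the genome build mm10. Per the file headers the Cell Ranger version was 3.0.2 for Sham B, IR D5 B and IR D5 C, 4.0.0 for Sham A, IR D5 A, IR D14 and IR D28, and 6.0.1 for IR H4, IR H12 and IR D1. No Sham library shares a version with the 3 earliest times, so version and time cannot be told apart there. The older version lists 31053 genes and the others 32285. The 30406 gene identifiers found in both were used, and they hold 99.6% to 100.0% of the UMIs of each library; 597 of them carry different symbols in the lists. Gene positions are from the GENCODE vM21 annotation of mm10, 1-based.

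The deposited counts hold 122151 barcodes and 982761944 UMIs, from 56105479 (Sham B) to 163390939 (IR D5 A) per library. Barcodes with at least 500 UMIs, at least 200 genes and at most 50% mitochondrial UMIs were kept, which left 105473. In all, 16580 barcodes were above the mitochondrial limit and 11531 below the UMI or gene minimum. A doublet score from simulated pairs of barcodes was computed in each library, and the barcodes with the highest scores were removed at 0.8% per 1000 barcodes (10819 in all). The remaining 94654 cells had median depths of 4456 (IR H4) to 9021 UMIs (IR D5 C). Counts of all libraries were scaled per cell and log-transformed, and cells were clustered with no batch correction on 30 principal components of 2000 variable genes (20 neighbours, Leiden clustering with igraph 0.11.9, resolution 1). Of the 42 clusters, 35 were named from markers of 19 cell classes fixed before the data were examined, and 7 (2117 cells, 2.24%) stayed unnamed for low UMI counts with no own marker among their leading genes, no clear lead of a class, or a majority of called doublets. Unnamed cells were 2.30%, 4.03% and 11.3% of IR D5 A, B and C and 0.215% and 0.106% of Sham A and B, and most (1330) were in cluster 23, whose best marker score was that of macrophages. Cell classes are called X-like throughout for this reason; the labels give no cell types. Of the 15 classes found, 6 had at least 30 cells in each Sham and IR D5 library and were tested for genes.

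Only Sham and IR D5 have more than 1 library, so only IR D5 against Sham was tested. UMI counts were summed per library and class and tested with the quasi-likelihood F test of edgeR 4.0.16 (TMM scaling, filterByExpr, robust fit), with Benjamini-Hochberg adjustment at 0.05. Standard errors (SE) of log2 changes were back-calculated as the absolute log2 change divided by the square root of the F statistic. Levels are UMI counts of a gene scaled to the UMIs of the class (CPM), computed from the deposited counts. Shares of cells were compared with an exact two-sided permutation test over the 10 splits of the 5 libraries, whose smallest possible p is 0.1, and with edgeR on cell counts. Single-library times have no test. There a gene was said to stand apart when its CPM was at least 4-fold above or below both Sham libraries with at least 50 UMIs in the higher one. The same rule between IR D5 libraries gave a yardstick. List medians were taken of log2 ratios to the Sham mean with 1 CPM added. Their percentiles among 10000 random lists matched on expression were computed but are not given below. Exact Poisson (levels) and exact binomial (shares) 95% intervals cover counting error only.

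Gene lists and all rules above were fixed before the data were examined. There were 25 lists with 508 entries, of which 507 matched a gene: tubule injury, proximal tubule transport, fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrially encoded, glycolysis, gluconeogenesis, immediate early, heat shock, ER stress, oxidative stress, hypoxia, NF-kB and cytokine, interferon response, antigen presentation, complement, cell cycle, p53 and arrest, matrix and fibrosis, cell death, inflammatory macrophage, repair or resident macrophage, endothelial activation, ribosomal protein, and a sex check that was not tested as a set. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg adjusted over the lists of a class). No list call in any class held when camera estimated the correlation. Genes named in proximal tubule-like cells are the 8 largest rises and 8 largest falls past the threshold with a mean CPM of at least 20, 16 fixed genes, and up to 4 members per list with the smallest adjusted p. In other classes they are the 5 largest each way that also reach at least the CPM of all other cells, and list members. At single times they are the 5 genes farthest from the nearer Sham library each way. Predicted genes were left out, and haemoglobin, Xist and Y-linked genes are named only as checks. A gene that the rule names in T cell-like cells is not reported here.

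RNA from other cells was measured as spill-over: the share of the other cells' CPM seen in proximal tubule-like cells, from markers of the other classes. The tests were checked on counts simulated from the real means and library sizes, with 200 changed genes. Changed genes were drawn only from well-covered ones, above a minimum expected count in the shallowest library. Recovery of weaker genes was not measured. With gene-wise dispersions in proximal tubule-like cells (13602 genes tested), 82% of 4-fold and 11% of 2-fold changes were recovered, and 14.7% of calls were false. With dispersions from the trend (13545 genes tested), 83% and 17% were recovered and 3.85% of calls were false. In macrophage-like cells (11610 genes, gene-wise) 73% of 4-fold changes were recovered with 8.99% false calls. Alternatives were DESeq2 1.42.0, other scaling, other gene and cell filters, no doublet removal, resolution 2, blocks for replicate letter and for Cell Ranger version, fits without each library, camera with an estimated correlation, fry, other folds and UMI minimums, each Sham library alone and another pseudocount. Chosen after the data were seen were runs without mitochondrially encoded genes, without genes higher in the other cells, with only calls having under 50% from spill-over, with every library thinned to the shallowest, and of shares without clusters with markers of another class. Python 3.11.15, scipy 1.17.1 and R 4.3.3 were used.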

Results

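Kidney cells of C57BL/6 mice were profiled by droplet single-cell RNA sequencing in 2 Sham libraries and in 8 libraries taken 4 hours to 28 days after ischemia-reperfusion (IR), an injury of the tubular epithelium. The series title concerns renal injury and fibrosis. Total depth was 119237286 UMIs in Sham A, 56105479 in Sham B, 83161890 at IR H4, 105652229 at IR H12, 93267064 at IR D1, 163390939, 81057793 and 82727595 at IR D5 A, B and C, 91319476 at IR D14 and 106842193 at IR D28. IR D5 (n = 3) was tested against Sham (n = 2). Every other time is 1 library with no replicate check.

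The share of proximal tubule-like cells, the reabsorbing epithelium of the cortex, was lower at IR D5 and that of immune cells higher, with no test passing. Cell numbers per kidney were not measured, and a larger share of 1 class lowers the others. Proximal tubule-like cells made up 82.6% ± 7.64 (SD, n = 2) of kept cells in Sham and 36.2% ± 19.5 (SD, n = 3) at IR D5, lower in all 3 libraries. Macrophage or monocyte-like cells made up 1.93% ± 0.655 and 30.2% ± 14.8, and T cell-like cells 1.95% ± 0.251 and 8.79% ± 2.48. Neutrophil-like cells, early phagocytes, were at 0.204% ± 0.288 and 3.53% ± 0.981, and dendritic-like cells, which present antigen to T cells, at 0.269% ± 0.273 and 3.45% ± 0.588. Fibroblast-like cells, the makers of collagen matrix, were at 0.0419% in Sham and 0.751% ± 0.606 at IR D5. Sham A and B held 5 and 2 such cells, and IR D5 A, B and C held 172, 13 and 48. The exact binomial intervals of IR D5 B (0.0838% to 0.269%) and Sham A (0.0174% to 0.125%) overlapped for this class. The macrophage-, T cell-, neutrophil-, dendritic- and fibroblast-like shares were each higher in all 3 IR D5 libraries than in both Sham libraries.

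The exact two-sided permutation test over 10 splits cannot go below 0.1. This exact permutation test gave p = 0.1 for T cell-, neutrophil- and dendritic-like cells and p = 0.2 for the other 3, with an adjusted value of 0.375 in each case (Benjamini-Hochberg over 15 classes). edgeR's quasi-likelihood test on cell counts gave log2 changes of 4.18 for fibroblast-, 4.07 for macrophage- and 3.75 for dendritic-like cells (adjusted p = 0.0939 each). The edgeR values were 4.20 for neutrophil-like (0.223), 2.25 for T cell-like (0.127) and -1.11 for proximal tubule-like cells (adjusted p = 0.442). Within Cell Ranger versions 4.0.0 and 3.0.2 the differences were -48.9 and -47.8 points for proximal tubule-like, 24.6 and 29.8 for macrophage-like and 9.80 and 5.27 for T cell-like cells, pooled 6.84. At resolution 2 a cluster of 2422 cells was named NK cell-like and the T cell-like difference was 3.75 points. B cell-like cells were at 0.483% and 1.24% (p = 0.2 by the exact permutation test) and distal convoluted or connecting tubule-like cells at 1.14% at IR D5, lower by 1.36 points (p = 0.2). Thick ascending limb-like cells were at 2.46% and 1.70%, endothelial-like at 1.98% and 2.64%, and intercalated-like at 2.95% and 1.53%. Thin limb-, collecting duct principal cell-, podocyte- and pericyte or smooth muscle-like cells differed by 0.378, 0.0577, 0.125 and -0.0736 points (p of 0.5 or more by the exact permutation test). Without Sham A the difference turned to 0.325 points for thick ascending limb-like and 0.856 for intercalated-like cells. Shares depend on which cells survive digestion, which was not measured.

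Across the single-library times the proximal tubule-like share was 71.8% (exact binomial 95% interval 71.0 to 72.6) at IR H4, 69.9% (69.0 to 70.8) at IR H12, 25.7% (24.8 to 26.6) at IR D1, 65.2% (64.2 to 66.2) at IR D14 and 75.2% (74.4 to 75.9) at IR D28, against 77.2% and 88.0% in Sham A and B. Macrophage-like cells were at 4.85% (4.46 to 5.26), 6.19% (5.74 to 6.66) and 24.2% (23.3 to 25.1) on the first day and at 9.29% (8.68 to 9.92) and 3.69% (3.36 to 4.04) at IR D14 and IR D28, against 1.47% and 2.40% in Sham. The neutrophil-like share was 8.38% (7.81 to 8.99) at IR D1, above each of the other libraries. No neutrophil-like cell was found among the 9314 cells of Sham A, where 3 cells would be 0.0322%. The exact binomial 95% interval of that share reaches 0.0396%. T cell-like cells were at 2.66% (2.33 to 3.02) at IR D1, 8.26% (7.69 to 8.86) at IR D14 and 4.88% (4.51 to 5.28) at IR D28, against 1.77% and 2.13% in Sham.

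**Figure D1:**
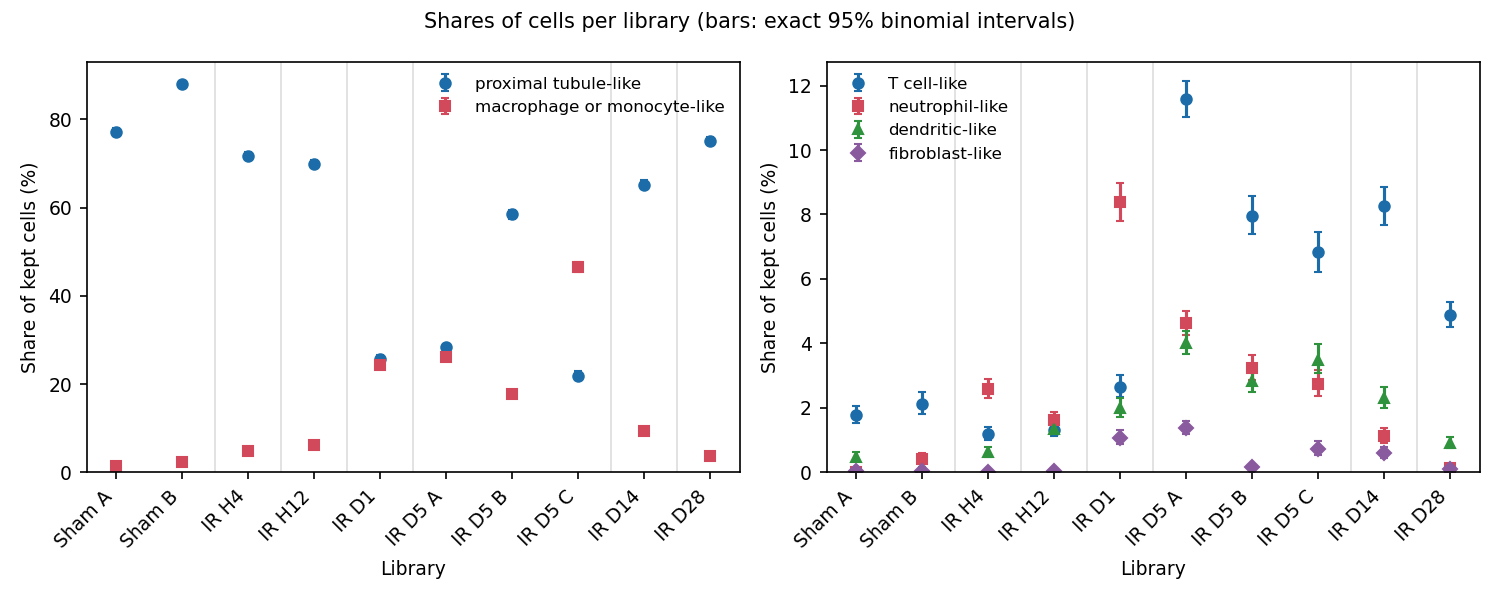
Share of kept cells (%, y axis) in each library (x axis) for proximal tubule- and macrophage-like cells (left) and T cell-, neutrophil-, dendritic- and fibroblast-like cells (right); points are libraries and bars exact binomial 95% intervals. Proximal tubule-like cells lie at 25.7% at IR D1 and 21.9% to 58.5% at IR D5, below 77.2% and 88.0% in Sham, while macrophage-like cells lie at 17.8% to 46.5% at IR D5.

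In proximal tubule-like cells at IR D5, the largest rises included those of an injury marker and a chemokine gene. Havcr1 (ENSMUSG00000040405; mm10 chromosome 11, 46735080 to 46779578, + strand, protein coding), the kidney injury marker KIM-1, rose from 0.317 to 220 CPM (log2 9.35 ± 0.73 SE, edgeR quasi-likelihood adjusted p = 0.00344), with 322, 203 and 134 CPM in IR D5 A, B and C. S100a6, a calcium-binding protein, rose from 0.924 to 520 CPM (8.99 ± 0.59, adjusted p = 0.000794). Ccl2, a chemokine that draws monocytes, rose from 0.834 to 146 CPM (7.22 ± 0.69, 0.00664), and Vcam1, an adhesion molecule (chromosome 3, 116109949 to 116129688), from 1.34 and 1.16 CPM in Sham A and B to a mean of 118 CPM (6.36 ± 0.61, 0.00612). Vim (vimentin; 7.09 ± 0.61, 0.00407), Anxa3 (7.15 ± 0.68, 0.00664), Plat (tissue plasminogen activator; 6.66 ± 0.57, 0.00350) and Serpina10 (6.67 ± 0.80, 0.0193) completed the 8 largest rises. The largest falls were smaller. Lpl (lipoprotein lipase) fell by 2.01 ± 0.34 from 376 to 108 CPM (adjusted p = 0.0237). By the same test Slc7a13 (an amino acid transporter) fell by 1.73 ± 0.35 (0.0452), Inmt (a methyltransferase) by 1.69 ± 0.29 (0.0237) and Degs2 by 1.61 ± 0.29 (0.0291). The other 4 were Azgp1 at -1.60, Nudt19 at -1.46, Aspdh at -1.46 and Fmo5 at -1.39 (adjusted p 0.0133 to 0.0480).

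In all, 329 genes rose and 24 fell of 13878 tested in this class (2126 at an unadjusted p under 0.05). All 353 had the same direction within both Cell Ranger versions. This is no separate check, since the genes were called on the same 5 libraries. For Havcr1 the changes within versions 4.0.0 and 3.0.2 were 10.52 and 8.15, and for Lpl -2.86 and -1.51. With the version as a term in the fit 1079 rose and 286 fell, by DESeq2 858 and 245, and with no low-count filter 656 and 125. Without 1 library they were 205 and 21 (Sham A), 200 and 58 (Sham B), 240 and 5, 179 and 15, and 236 and 0 (IR D5 A, B and C). In fits without a Sham library the lone one is assumed to vary like IR D5. The calls of Serpina10 (adjusted p up to 0.112, lost without Sham A, Sham B or IR D5 B) and Vcam1 (0.0928, without either Sham library) depended on single libraries. Each of the 8 falls was lost in at least 1 such fit, at 0.0529 (Aspdh, without IR D5 B or C) to 0.197 (Azgp1). The others were Lpl (0.0765, Sham A, IR D5 A or C), Slc7a13 (0.134) and Nudt19 (0.102) and Fmo5 (0.0878, each Sham A or any IR D5 library). Inmt (0.0830, IR D5 A or C) and Degs2 (0.0851, Sham B, IR D5 A or C) completed them, and for Azgp1 the libraries were Sham A, Sham B and IR D5 A and C. Most proximal tubule-like cells of Sham (92.4% and 95.9%) and of IR D5 (60.7%, 79.8% and 83.2%) lay in clusters 1, 3, 4, 5 and 6, and cluster 20, led by Havcr1, C3 and Krt20 among its top genes, held 26.4%, 6.42% and 3.52% of those of IR D5 A, B and C and 3.16% and 0.120% in Sham. At resolution 2 a cluster of 917 cells led by Havcr1 and C3 was unnamed, and 80 genes passed in this class, 79 higher and 1 lower. Of the named genes of all classes that passed, 27 did not pass at resolution 2 and 66 still did. With no doublet removal 29 did not pass and 65 still did.

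**Figure D2:**
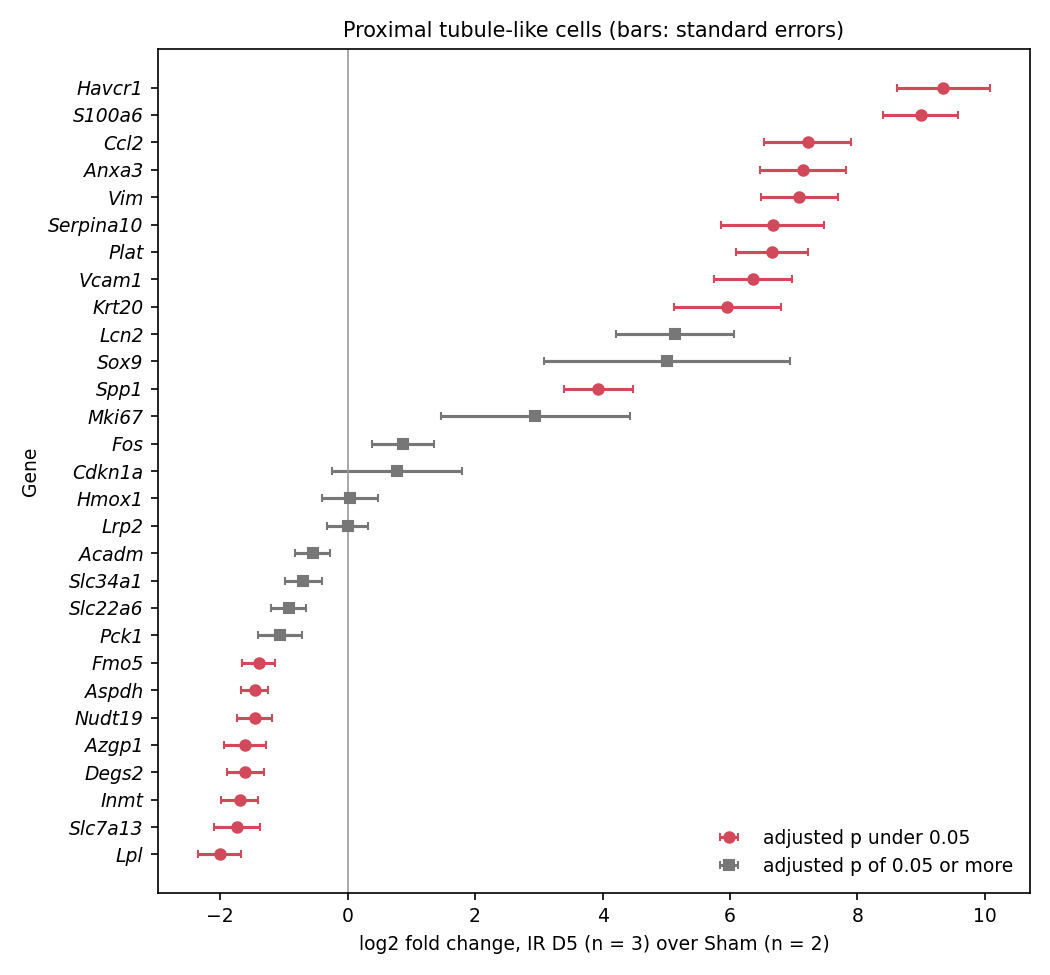
Log2 fold change of IR D5 (n = 3) over Sham (n = 2) in proximal tubule-like cells (x axis) for the named and fixed genes (y axis), with standard errors as bars; red circles passed an adjusted p of 0.05 and grey squares did not. Havcr1 is at 9.35, Spp1 at 3.94 and Lpl at -2.01, and Lcn2 at 5.14 did not pass.

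Of the fixed genes, Spp1 (osteopontin, a secreted phosphoprotein; chromosome 5, 104435118 to 104441050) rose from 499 to 8660 CPM (log2 3.94 ± 0.54, edgeR quasi-likelihood adjusted p = 0.0116) and the keratin Krt20 from 0.236 to 18.8 CPM (5.96 ± 0.84, 0.0290, lost without IR D5 B, 0.0824). Lcn2 (NGAL, a urinary injury marker) was at 0.278 and 11.6 CPM (5.14 ± 0.93) and did not pass (0.0552). Nor did Sox9 (5.01 ± 1.93, 0.376), the cell cycle inhibitor Cdkn1a (0.77 ± 1.02, 0.831), the proliferation marker Mki67 (2.95 ± 1.48, 0.486), Fos (0.87 ± 0.48, 0.477) or Hmox1 (0.04, 0.985). Mki67 was at -0.05 within version 4.0.0 and 5.36 within 3.0.2. Among genes of the mature tubule, none of the phosphate transporter Slc34a1 (-0.70 ± 0.29, 0.294), the endocytic receptor Lrp2 (0.00, 1.00), the organic anion transporter Slc22a6 (-0.92 ± 0.28, 0.131), Acadm (-0.55, 0.417) or Pck1 (-1.06 ± 0.34, 0.161) passed. Lrp2 was at -0.49 within version 4.0.0 and at 0.14 within 3.0.2. Of the named genes of all classes that did not pass, 18 passed with the version as a term, 20 with a replicate block and 17 by DESeq2. In the same order 10, 8 and 11 still did not pass, and 1 each changed direction.

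The tubule injury list rose as a group in proximal tubule-like cells: 10 of 24 tested members rose and none fell (18 higher adjusted over the list alone), with a median log2 change of 3.77 (camera, adjusted p = 7.96e-41; adjusted p = 0.128 with an estimated correlation). Beside Havcr1, S100a6, Vim, Vcam1, Spp1 and Krt20 they were Cd44 (a hyaluronan receptor; 7.28 ± 0.47, adjusted p = 0.000794 by edgeR), Dcdc2a, Sema5a and Anxa1. The NF-kB and cytokine list had 7 of 23 members higher (17 over the list alone; median 2.02, camera adjusted p = 1.21e-22, 0.176 with an estimated correlation), among them Ccl2, Relb (an NF-kB subunit; 2.76, 0.0108) and the macrophage growth factor Csf1 (3.99, 0.0108, lost without either Sham library, 0.0945). Spill-over of RNA from the other cells could supply a median of 0.607% of the IR D5 level of the 10 injury genes and 3.40% of that of the 7 cytokine genes. For single genes it was 0.0361% for Havcr1, 1.56% for S100a6 and 3.89% for Ccl2, but 123% for Il1b, which also passed (4.33, 0.00365), and 38.9% for Lcn2.

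Immune and matrix lists were also higher in this class, where markers of macrophages moved too. In all 8 of 13 tested macrophage markers rose, from a median of 0.358 to 3.41 CPM. So did 3 of 6 thin limb markers (median log2 change 2.12) and 1 of 4 podocyte markers (2.61). The 4 neutrophil markers had a median of 2.98 with 0 passing. Markers of the thick ascending limb and the distal convoluted or connecting tubule had medians of -0.38 and -0.79. The interferon response list had 4 of 22 members higher (10 over the list alone; median 1.47, camera adjusted p = 1.38e-09, 0.194 with an estimated correlation). They were Ifi27l2a (3.34, adjusted p = 0.00763 by edgeR, spill-over 94.1%), Ifit2 (2.64, 0.0247, lost without Sham A, IR D5 A or B, up to 0.0878), Bst2 (2.03, 0.0452, lost without Sham A, Sham B or IR D5 B, up to 0.248) and Irf7 (adjusted p = 0.0482, lost without any 1 library, up to 0.126). Antigen presentation had no member past the threshold over all genes and 15 of 16 over the list alone (median 2.11, camera adjusted p = 1.38e-11, 0.228 with an estimated correlation). H2-Eb1, at 3.50 (0.0642), had a spill-over of 28.1%. Complement had 1 of 13 higher, with 8 higher and 1 lower over the list alone (median 2.02; 5.4e-07, 0.194 with an estimated correlation). That was C3, the central complement protein (7.65 to 207 CPM, 4.56 ± 0.74, 0.0425, lost without Sham A, Sham B or IR D5 B, up to 0.302, spill-over 0.120%).

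Matrix and fibrosis had 3 of 21 higher (13 over the list alone; median 1.89, camera adjusted p = 1.48e-09, 0.194 with an estimated correlation). These were Tgfb1 (2.78, adjusted p = 0.0108 by edgeR, spill-over 19.1%), Fn1 (fibronectin; 4.02, 0.0149, lost without IR D5 B, 0.0526, spill-over 39.0%) and Col18a1 (1.87, 0.0366, lost without Sham A, Sham B or IR D5 B, up to 0.151). Cell death had 5 of 19 higher (9 over the list alone; median 0.91; 8.62e-08, 0.176 with an estimated correlation). It was led by the inflammasome genes Casp4 (5.12, 0.0141, lost without Sham B, 0.0588) and Gsdmd (5.12, 0.0149). Inflammatory macrophage had 7 of 15 higher (14 over the list alone; median 3.84; 8.06e-25, 0.128 with an estimated correlation). They included Il1b, Ccl2 and Ccl3 (3.33, 0.0149, spill-over 104%). Repair or resident macrophage had 5 of 18 higher (7 over the list alone; median 1.36; 2.66e-07, 0.176 with an estimated correlation). Among them were Cd9 (2.55, 0.0116, lost without Sham B, 0.0518) and Trem2 (2 UMIs in Sham and 169 at IR D5, ratio 92.1, counting interval 25.1 to 767; 0.0227, spill-over 134%). Endothelial activation had 3 of 12 higher (5 over the list alone; median 1.41; 1.11e-07, 0.128 with an estimated correlation). These were the vasoconstrictor peptide gene Edn1 (4.63, 0.00407), Vcam1 and Tgfb1. Cell cycle had 2 of 30 higher (2 over the list alone; median 1.86; 1.64e-07, 0.294 with an estimated correlation). The pair was Mcm3 (2.72, 0.0356, lost without Sham A, IR D5 B or C, up to 0.102) and Ccnb2 (3.36, 0.0383, lost without Sham B, IR D5 B or C, up to 0.101). Over all 329 rises the spill-over share had a median of 4.96%, and 256 were under 50%. In all 58 of the 329 had a CPM at least as high as the other cells together.

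Lists of tubular function and mitochondrial energy shifted downward by less. Proximal tubule transport had 1 of 29 members lower, Slc7a13 (1 over the list alone; median -0.40, camera adjusted p = 2.23e-05, 0.128 with an estimated correlation). Slc22a8 was at -1.10 (adjusted p = 0.119 by edgeR). Fatty acid oxidation, the main fuel pathway of this segment, had 0 of 28 past the threshold by either adjustment (median -0.52; 2.23e-05, 0.174 with an estimated correlation). Acot12 was at -0.93 (adjusted p = 0.0792 by edgeR) and Acads at -0.84 (0.117). Nuclear oxidative phosphorylation genes had 0 of 32 (0 over the list alone; median -0.42; 5.1e-05, 0.550 with an estimated correlation, and up to 0.218 without 1 library). Sdhb was at -0.80 (adjusted p = 0.174 by edgeR) and Uqcrc1 at -0.70 (0.229). Gluconeogenesis had 0 of 7, with 5 lower and 1 higher over the list alone (median -0.79; 0.00301, 0.176 with an estimated correlation). G6pc was at -1.13 (adjusted p = 0.137 by edgeR) and Slc37a4 at -0.89 (0.126). Markers of the proximal tubule itself had a median of -0.64, with 1 of 20 lower.

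The immediate early list holds transcription factors and other genes induced within minutes of a stimulus. In proximal tubule-like cells it had 0 of 20 members past the threshold (0 over the list alone) with a median of 0.91 (camera adjusted p = 0.00294, 0.528 with an estimated correlation, up to 0.129 without 1 library). Klf4 was at 1.39 (adjusted p = 0.126 by edgeR) and Klf6 at 1.01 (0.148), and the list median was 1.70, 1.12 and 0.06 in IR D5 A, B and C. Glycolysis had 3 of 16 higher (5 over the list alone), with a median of -0.25 but a mean of 0.76 and an upward test that did not pass (0.0897). The 3 were Hk2 (hexokinase 2; 5.37, 0.00612), Pkm (3.14, 0.0116, lost without Sham B, 0.0588) and Pfkp (1.43, 0.0250, lost without Sham B or any IR D5 library, up to 0.0734). ER stress had 1 of 17 higher (1 over the list alone; median -0.02, mean 0.25, upward test 0.853), Asns (0.0231, lost without Sham B, IR D5 A or B, up to 0.0609). No member of the other lists passed. They were mitochondrially encoded (median -0.04, mean 0.11, downward test 0.763), heat shock (-0.08, 0.39, downward, 0.853), oxidative stress (-0.14, 0.26, downward, 0.627), hypoxia (-0.20, adjusted p = 0.360), p53 and arrest (0.31, 0.153, with 1 member over the list alone) and ribosomal protein (-0.03, 0.495). With fry, which tests only whether a list's genes move one way on balance, 8 lists passed, each at an adjusted p of 0.0338.

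Thick ascending limb-like cells, the salt-reabsorbing segment of the loop of Henle, also raised injury genes at IR D5. In all 123 genes rose and 84 fell of 7304 (931 at an unadjusted p under 0.05). All had the same direction within both Cell Ranger versions, again in the libraries that called them. The libraries held 450362 to 5765876 UMIs in this class. Lcn2 (chromosome 2, 32384633 to 32388252) rose from 24.6 to 1818 CPM (log2 6.02 ± 0.44, edgeR quasi-likelihood adjusted p = 1.19e-07), the secreted chaperone Clu from 77.1 to 2309 CPM (4.79 ± 0.44, 1.55e-05) and Spp1 from 2456 to 30391 CPM (3.55 ± 0.36, 5.28e-06). Ccl20, a chemokine for lymphocytes and dendritic cells, had no UMI in Sham and 51.1 CPM at IR D5, at least 51.5-fold higher against a floor of 3 UMIs over the group (1.55e-06). The cytokine Lif had 1 Sham UMI and a ratio of 75.1 (counting interval 13.3 to 2984; 0.000106), and Sprr1a 1 Sham UMI and a ratio of 440 (78.8 to 17395; 0.00233, lost without either Sham library, 0.234). Egf, the growth factor this segment secretes into urine, fell from 5521 to 1255 CPM (-2.25 ± 0.44, 0.0259, lost without Sham A, IR D5 A or C, up to 0.112). Ppp1r1b fell by 1.95 ± 0.28 (0.000354), Tmem86a by 2.21 ± 0.39 (0.00225, lost without IR D5 A, 0.0581), Inpp5j by 1.97 ± 0.34 (0.00190, lost without IR D5 A, 0.0505) and Pcsk6 by 1.86 ± 0.39 (0.0182, lost without Sham A, IR D5 A or B, up to 0.374). Without IR D5 A 60 genes rose and 12 fell, and without IR D5 B 86 and 21.

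In the same cells the tubule injury list had 10 of 22 members higher (16 over the list alone; median 1.98, camera adjusted p = 6.19e-31, 0.136 with an estimated correlation). Among them were Lcn2, Spp1, Clu and Lgals3 (2.49, adjusted p = 8.35e-05 by edgeR). NF-kB and cytokine had 3 of 15 (10 over the list alone; median 1.75; 2.98e-18, 0.136 with an estimated correlation). The 3 were Ccl20, Cxcl2 (5.14, 3.06e-06; 84.6 CPM against 1196 in the other cells) and Cxcl16 (1.64, 0.00436, lost without IR D5 B, 0.0570). Matrix and fibrosis had 2 of 11 (5 over the list alone; median 1.15; 7.74e-06, 0.136 with an estimated correlation). Both passed by edgeR, Pdgfa (1.36, 0.00956, lost without Sham A, IR D5 A or B, up to 0.0784) and Col4a1 (1.49, 0.0310, lost without Sham B or any IR D5 library, up to 0.258). Antigen presentation had 2 of 11 (4 over the list alone; median 0.79; 1.57e-05, 0.368 with an estimated correlation). They were H2-Ab1 (3.16, 0.00295; 26.3 CPM against 2045 in the other cells, lost without Sham A or IR D5 A, up to 0.188) and Psmb8 (1.64, 0.0141, lost without Sham A, IR D5 A or B, up to 0.240). Cell cycle had 3 higher and 1 lower of 8 (median 0.40; 0.000712, 0.272 with an estimated correlation, up to 0.840 without 1 library). Stmn1 was at 2.76 (0.000354) and Ccnd1 at -1.12 (0.0241, lost without any 1 library, up to 0.163). The mitochondrially encoded list had 0 of 13 (5 lower over the list alone; median -0.75; 4.05e-05, 0.461 with an estimated correlation).

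Distal convoluted or connecting tubule-like cells, which fine-tune salt and calcium, had 37 genes higher and 0 lower at IR D5 of 7750 tested by edgeR (495 at an unadjusted p under 0.05). DESeq2 called 56 higher and 1 lower, and edgeR with the version as a term 156 and 56. Without Sham A 150 rose and 57 fell, and without Sham B 86 and 69. Lcn2 had no UMI in Sham and 1232 CPM at IR D5, at least 1039-fold higher against the 3-UMI floor (edgeR quasi-likelihood, adjusted p = 2.12e-09). Dcdc2a, a doublecortin-domain gene, rose from 5.63 to 88.8 CPM (3.73 ± 0.41, 0.000126), Emp2 from 3.25 to 37.6 CPM (3.12 ± 0.54, 0.00650) and Spp1 from 1948 to 11512 CPM (2.47 ± 0.48, 0.0410, lost without IR D5 A or C, up to 0.115). Sema3c had 1 Sham UMI and a ratio of 66.3 (counting interval 11.5 to 2656; 0.0114, lost without IR D5 B, 0.0940). Tubule injury had 5 of 17 members higher (10 over the list alone; median 1.13, camera adjusted p = 1.09e-33, 0.178 with an estimated correlation). They included Anxa2 (3.72, 0.00354) and Tpm1 (2.42, 0.00369). NF-kB and cytokine had 3 of 14 (4 over the list alone; median 1.87; 1.01e-13, 0.242 with an estimated correlation). These were Cxcl10 (4.63, 0.00705), Cxcl16 (3.19, 0.00369, lost without IR D5 A, 0.0885) and Tnfrsf12a (2.44, 0.0364, lost without IR D5 A, 0.119). Antigen presentation had 2 of 10 (7 over the list alone; median 1.73; 2.7e-11, 0.242 with an estimated correlation). The pair was H2-Ab1 (2.55, 0.0181, lost without IR D5 A, 0.576) and H2-D1 (1.56, 0.0410, lost without IR D5 A or B, up to 0.295), both below the other cells (28.2 against 2019 and 225 against 1010 CPM). The libraries held 399932 to 1891565 UMIs in this class, and the count was 24 without IR D5 A, 207 without Sham A and 155 without Sham B, with the lone Sham library assumed to vary like IR D5.

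Endothelial-like cells, the lining of renal vessels, had no gene past the threshold of edgeR's quasi-likelihood test among 8624, with 260 at an unadjusted p under 0.05 and 16 by DESeq2. With the Cell Ranger version as a term 70 genes passed, 53 higher and 17 lower. In simulated data with gene-wise dispersion 46% of 4-fold changes were recovered in this class. Those changes were placed only in well-covered genes, so recovery of weaker genes was not measured. The endothelial activation list had 0 of 18 members past the threshold (1 over the list alone; median -0.03, mean 0.14, upward test, camera adjusted p = 0.485). Gluconeogenesis, a proximal tubule pathway, was lower (0 of 6, with 1 over the list alone; median -1.13, camera adjusted p = 1.76e-05, 0.387 with an estimated correlation), and inflammatory macrophage genes, typical of another class, were higher (0 of 8, with 2 over the list alone; median 1.74; 5.21e-07, 0.661 with an estimated correlation). Proximal tubule markers made up 0.162% and 0.154% of endothelial-like UMIs in Sham and 0.188%, 0.0358% and 0.0350% in IR D5 A, B and C.

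Macrophage or monocyte-like cells of IR D5 had 12 genes higher and 2 lower of 12031 by edgeR (1217 at an unadjusted p under 0.05). The balance was less one-sided in other fits, with 88 higher and 103 lower by DESeq2, 457 and 358 with the version as a term and 62 and 75 without IR D5 A. Arg1 (arginase 1, a gene of wound-healing macrophages; chromosome 10, 24915221 to 24927484) had no UMI in Sham and 194 CPM at IR D5, at least 91.6-fold higher against the 3-UMI floor (edgeR quasi-likelihood, adjusted p = 0.00596). Fabp5, a fatty acid carrier, rose from 18.7 to 646 CPM (5.13 ± 0.68, 0.0168), the NAD-consuming enzyme gene Cd38 from 8.67 to 167 CPM (4.28 ± 0.49, 0.00596), and the lipid receptor gene Trem2 from 75.5 to 571 CPM (2.95 ± 0.43, 0.0255). By the same test the lysosomal protease gene Ctsd rose from 166 to 1678 CPM (3.33 ± 0.50, 0.0259) and Cfp (properdin) from 20.4 to 238 CPM (3.58, 0.00596). Syngr1 and Nxpe5 each had 2 Sham UMIs, with ratios of 45.9 (counting interval 12.7 to 379; 0.0168) and 34.7 (9.60 to 287; 0.0134). The falls were Adrb1, the beta-1 adrenergic receptor gene, from 63.3 to 5.95 CPM (-3.31 ± 0.41, 0.00923), and Srpk3 from 13.9 to 1.04 CPM (-3.67 ± 0.57, 0.0294), which was named after its values were seen. The calls named here were lost without Sham A or Sham B, at adjusted p of up to 0.260 (Arg1, Fabp5, Nxpe5, Cfp, Adrb1) to 0.449 (Srpk3, also lost without IR D5 B), with 1 and 0 genes left in those fits, in which the lone Sham library is assumed to vary like IR D5. Without IR D5 A 137 genes passed and without IR D5 C 79.

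The repair or resident macrophage list had 4 of 21 members higher in these cells, with 13 higher and 1 lower over the list alone (median 1.53, camera adjusted p = 2.12e-22, 0.367 with an estimated correlation). The 4 were Arg1, Fabp5, Trem2 and Ctsd. Inflammatory macrophage genes had 0 of 17 (2 higher and 1 lower over the list alone), with a median of -0.06, a mean of 0.24 and an upward test that did not pass (0.745). Antigen presentation was lower (0 of 16 by either adjustment; median -0.60; 2.33e-05, 0.485 with an estimated correlation), with Cd74 at -1.40 (adjusted p = 0.329 by edgeR) and H2-Ab1 at -1.48 (0.297). Immediate early genes were lower too (0 of 20, with 1 higher and 1 lower over the list alone; median -0.71; 0.000127, 0.421 with an estimated correlation), with Atf3 at -1.27 (0.329). Cell cycle was higher (0 of 26, 4 over the list alone; median 0.76 with genes at 0 in Sham at their bound, camera adjusted p = 2.33e-05, 0.421 with an estimated correlation). Proximal tubule transport genes were lower in these cells (0 of 25, 9 over the list alone; median -1.55; 7.49e-13, 0.421 with an estimated correlation). Proximal tubule markers made up 0.270% and 0.143% of their UMIs in Sham and 0.0249% to 0.0521% at IR D5. Different clusters held the class. Cluster 13 had 64.2% of these cells in Sham A and 86.8% in IR D5 A, while cluster 2 had 82.4% in Sham B and 90.3% and 95.9% in IR D5 B and C. Sham libraries held 137 and 159 cells and 597308 and 823134 UMIs in this class.

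T cell-like cells of IR D5 had 4 genes higher and 3 lower of 9909 (489 at an unadjusted p under 0.05). Simulated data with no change gave 9 calls in this class with gene-wise dispersion and 0 with dispersions from the trend. Several other fits had more falls than rises, with 9 higher and 26 lower by DESeq2, 27 and 70 with no low-count filter, 30 and 105 with the version as a term and 9 and 81 without IR D5 A. All 4 rises were class II antigen presentation genes, which are typical of other immune cells. Cd74 rose to 234 CPM (3.60 ± 0.46, edgeR quasi-likelihood adjusted p = 0.0437) and was at 5687 CPM in the other cells. H2-Eb1 had 1 Sham UMI (ratio 70.6, counting interval 12.6 to 2790; 0.0437), H2-Aa 2 (36.3, 10.0 to 300.3; 0.0469), and H2-Ab1 rose by 4.38 ± 0.65 (0.0469). The falls included Clec2h (-3.88 ± 0.54, edgeR adjusted p = 0.0437) and Selenbp1 (-2.93 ± 0.43, 0.0437). Every T cell-like cluster had markers of another class among its 10 leading genes. Cluster 7, of 4482 cells, had a marker score of 5.55 for NK cells and 4.00 for T cells, so the class may hold both. All 7 genes were higher in the other cells than in this class, and those named here were named after their values were seen. The count was 0 without IR D5 B, where all 7 were lost (adjusted p up to 0.592 for Selenbp1), and 3 without Sham A. The antigen presentation list had 4 of 16 higher (4 over the list alone; median 0.28, camera adjusted p = 2.46e-11, 0.280 with an estimated correlation). Cell cycle had 0 of 30 (0 over the list alone; median 0.74; 8.83e-10, 0.536 with an estimated correlation) and gluconeogenesis had 1 of 7 lower (4 over the list alone; median -1.69; 2.02e-15, 0.280 with an estimated correlation). Cluster 39, with the cell division genes Top2a and Birc5 among its top genes, held 0% and 25.5% of the class in Sham A and B. In IR D5 A, B and C it held 4.81%, 3.65% and 6.43%, above Sham A but below Sham B. Proximal tubule markers made up 0.310% and 0.267% of T cell UMIs in Sham and 0.0401% to 0.186% at IR D5.

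On the first day after IR, Krt20 and Havcr1 stood above Sham in proximal tubule-like cells, each library set beside the Sham pair with no test. At IR H4, 193 genes stood apart as higher and 29 as lower. Krt20 was at 93.3 CPM (exact Poisson 95% interval 90.6 to 96.0), 221-fold above the nearer Sham library. Next were the AP-1 factor Fosl1 (46.1 CPM, 155-fold), the lipid kinase gene Sphk1 (19.4 CPM, 113-fold), Havcr1 (40.0 CPM, 38.3 to 41.8, 81.3-fold) and the metallothionein Mt2 (364 CPM, 68.5-fold). Hmox1, the heme-degrading enzyme gene of oxidative stress, was at 1590 CPM (1579 to 1601) against 66.2 and 34.8 in Sham, and Cdkn1a at 248 against 33.4 and 10.7. At IR H4 Spp1 (361 CPM against 504 and 494), Vcam1 (0.788 against 1.34 and 1.16) and Lcn2 (0.868 against 0.360 and 0.197) did not stand apart. The 5 lowest were Smco3, Ifit1, Cish, Ccno and the vitamin D-activating enzyme gene Cyp27b1 (0.384 CPM against 9.02 and 2.78). Sphk1 and Mt2 were at 45.5 and 1515 CPM in the other cells of the library.

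At IR H12 251 genes stood apart as higher and 102 as lower, and at IR D1 275 and 136. Havcr1 was at 273 CPM (269 to 278), 555-fold above the nearer Sham library, and then at 435 CPM (427 to 443), 883-fold. Krt20 was at 77.1 and 28.4 CPM, Hmox1 at 135 and 106 (not apart), and Spp1 at 4489 and 21736. Vcam1 was at 2.30 CPM at IR H12, not apart, and at 17.7 at IR D1. Lcn2 was at 21.3 and 56.9 CPM, apart at both (59.1- and 158-fold). Spill-over, which could supply 38.9% of the Lcn2 level at IR D5, is not given for Lcn2 at these times. At IR H12 Osmr, Saa1 and Slc25a24 followed Havcr1 and Krt20, at 6.09, 7.88 and 9.32 CPM. At IR D1 the next were Sprr1a (19.4 CPM; 3 Sham UMIs), S100a6 (306 CPM, 296-fold), Dysf (9.72 CPM; 2 Sham UMIs) and the acute-phase gene Saa1 (18.5 CPM, 169-fold). The lowest at IR H12 were Akr1c18, Smcp, Vmn1r20, Ccdc170 and Cyp7b1. At IR D1 they were the organic anion transporter Slc22a7 (0.204 CPM, interval 0.0663 to 0.476, against 23.4 and 24.5), Cyp7b1 (0.122 CPM), the brush border protease gene Mep1b (0.204 CPM, 75.7-fold lower), Slc7a13 (2.94 CPM against 370 and 198) and Vmn1r18. Slc34a1 was at 3018, 1702 and 1038 CPM at IR H4, IR H12 and IR D1 against 2896 and 4719 in Sham, and stood apart at no time. Different clusters held these cells. Clusters 10 and 11 had 89.1% at IR H4, and clusters 8, 9 and 18 had 95.8% at IR H12 and most at IR D1, while clusters 1, 3, 4, 5 and 6 had 4.57%, 1.42% and 1.56%. Beside these counts, each IR D5 library against the other 2 gave 148 higher and 20 lower (A), 15 and 1 (B) and 2 and 37 (C). Counts of Saa1, Vmn1r18, Vmn1r20, Akr1c18 and Mt2 may include reads of similar family members and are uncertain.

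**Figure D3:**
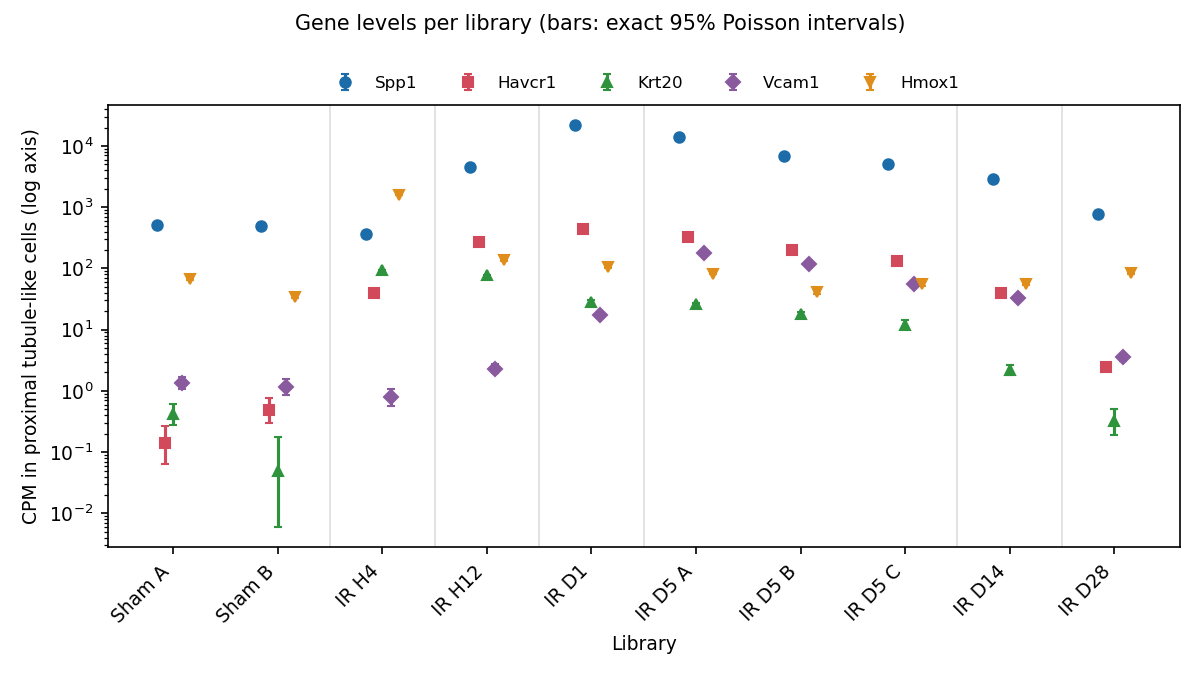
CPM (log axis) of 5 genes in proximal tubule-like cells of each library (x axis); points are libraries and bars exact Poisson 95% intervals. Hmox1 is at 1590 CPM at IR H4, Havcr1 at 435 CPM at IR D1 and 134 to 322 CPM at IR D5, and Vcam1 at 17.7 CPM at IR D1 and 118 CPM on average at IR D5.

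By the late times fewer genes stood apart from Sham, with 161 higher and 7 lower at IR D14, and 86 higher and 5 lower at IR D28. Against both Sham libraries IR D5 A, B and C had totals of 632, 354 and 184. Set against the other 2 IR D5 libraries, they had totals of 168, 16 and 39. Neither late total (168 and 91) was above the count of IR D5 A, but both were above those of IR D5 B and C. IR D5 A differs from B and C in Cell Ranger version, so its count is no plain measure of spread within 1 group. Havcr1 was at 39.0 CPM (37.3 to 40.9) at IR D14 and 2.46 (2.08 to 2.90) at IR D28, against 0.141 and 0.493 in Sham. Vcam1 was at 33.5 and 3.53 CPM against 1.34 and 1.16 in Sham, Spp1 at 2938 and 775, and Krt20 at 2.22 and 0.321. The highest at IR D14 besides Havcr1 were the serpins Serpina6 (5.33 CPM; 1 Sham UMI) and Serpina10 (17.6 CPM, 41.7-fold), Ccl12 (1.96 CPM against 345 in the other cells) and Hsd17b14 (2.45 CPM). The lowest were the anion transporters Slco1a4 and Slco1a1 (17.7 CPM, interval 16.5 to 19.0, against 161 and 86.9), Nat8f5, Cyp4a12a (6.99 CPM against 47.1 and 33.8) and Azgp1 (15.5 CPM against 73.5 and 69.7), several of which have similar family members that may share reads. At IR D28 the highest were Fst (4.32 CPM; 2 Sham UMIs) and 4 genes of dividing cells: Neil3, Melk, Tpx2 (4.79 CPM) and Hmmr (13.1 CPM, 14.5-fold), with Mki67 at 22.2 CPM. The lowest were Cish (1.72 CPM), Depp1, Azgp1 (16.1 CPM) and the BMP-responsive genes Id1 (13.7 CPM against 100.4 and 61.3) and Id3. Clusters 1, 3, 4, 5 and 6 held 84.7% of proximal tubule-like cells at IR D14 and 92.4% at IR D28, and cluster 24 held 8.31% at IR D14. Cluster 33, led by Hmmr and Mki67 and with 20.1% called doublets, held 1.74% of these cells at IR D28 against 0.167% and 0.0514% in Sham. It held 0.477%, 0.517% and 1.66% in IR D5 A, B and C and 0.143% at IR D14.

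Gene lists in proximal tubule-like cells had different values over the libraries, as medians of log2 ratios to the Sham mean with no test between times. Tubule injury was at 0.78, 2.20 and 2.68 at IR H4, IR H12 and IR D1. It was at 4.21, 2.79 and 2.30 in IR D5 A, B and C, and at 1.54 and 0.63 at IR D14 and IR D28. NF-kB and cytokine genes were at 0.40, 1.03 and 1.47 on the first day, at 2.53, 2.07 and 1.05 at IR D5 and at 0.74 and 0.02 later. Matrix and fibrosis genes were at 1.07, 1.07 and 1.27, at 1.86, 1.09 and 0.74, and at 0.65 and 0.34. Oxidative stress genes were at 0.29, 0.55 and 0.89 on the first day, at -0.03, -0.32 and 0.05 in IR D5 A, B and C and at 0.06 and -0.01 at IR D14 and IR D28. Transport genes were at -0.10, -0.48 and -0.37 on the first day, at -0.41, -0.16 and -0.35 at IR D5 and at 0.15 and 0.06 late. Fatty acid oxidation was at -0.23, 0.43 and 0.15, then at -0.41, -0.17 and -0.30 at IR D5, and at 0.14 and 0.05. The median over all genes was 0.12, 0.21 and 0.13 at the first 3 times, 0.07, 0.21 and 0.03 at IR D5 and 0.07 and 0.05 late. Many of these list medians at single times depended on which Sham library was used.

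**Figure D4:**
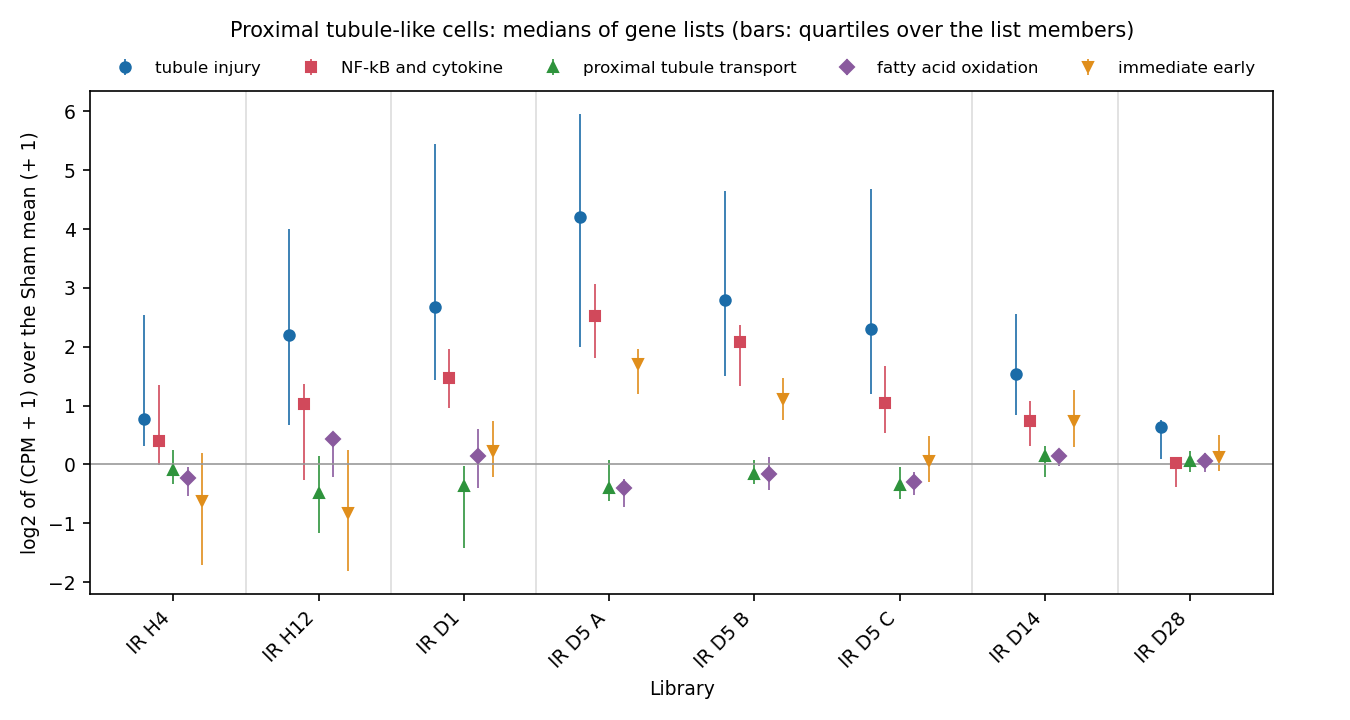
Median log2 ratio to the Sham mean (y axis) of 5 gene lists in proximal tubule-like cells of the 8 IR libraries (x axis), with bars from the lower to the upper quartile over the members. Tubule injury is above 0 in every library, from 0.63 at IR D28 to 4.21 in IR D5 A, and immediate early genes are at -0.82 at IR H12.

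In macrophage or monocyte-like cells list medians differed between the libraries of different times, which were not tested against each other. Inflammatory macrophage genes, cytokines and chemokines of recruited cells, were at 1.61, 1.28 and 1.37 at IR H4, IR H12 and IR D1. They were at -0.13, 0.34 and -0.93 in IR D5 A, B and C and at -0.09 and -0.40 at IR D14 and IR D28. Repair or resident macrophage genes were at -0.35, 0.27 and 0.43 on the first day, at 1.20, 1.33 and 2.07 at IR D5 and at 1.36 and 0.78 later. The median over all genes in these cells was 0.18, 0.33 and 0.28 on the first day, -0.26, 0.23 and 0.13 at IR D5 and 0.08 and 0.10 late, so the repair values at IR H12 and IR D1 were near it. Antigen presentation was at -0.82, -0.90 and -1.40 on the first day, at -0.29, -0.37 and -1.14 at IR D5 and at -0.37 and -0.04 late. Cluster 16 of these cells, led by Chil3 and the monocyte receptor gene Ccr2, held 43.2% at IR H4, 32.6% at IR H12 and 65.9% at IR D1. Cluster 2 held 82.7% at IR D14 and 85.4% at IR D28. The first-day libraries share a Cell Ranger version that no Sham library has.

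**Figure D5:**
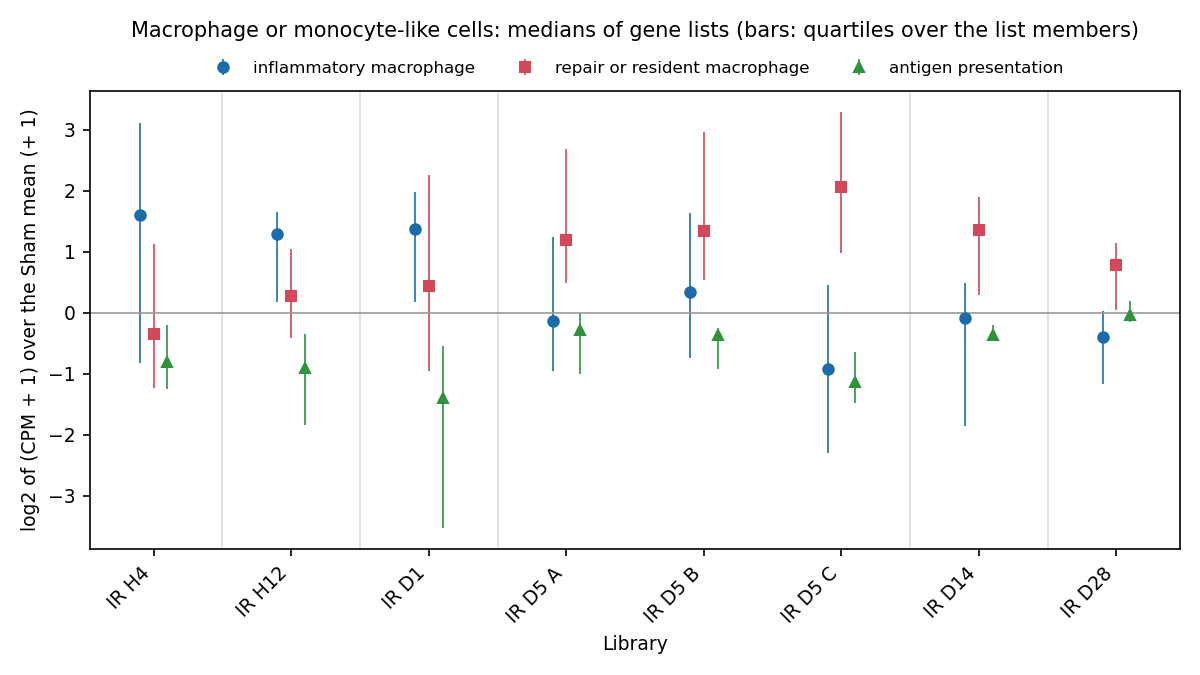
Median log2 ratio to the Sham mean (y axis) of 3 gene lists in macrophage or monocyte-like cells of the 8 IR libraries (x axis), with bars from the lower to the upper quartile over the members. Inflammatory genes are at 1.61 at IR H4 and at -0.93 to 0.34 at IR D5, and repair or resident genes at 1.20 to 2.07 at IR D5.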

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

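The tests of Xist and of handling below were chosen after the result they measure was seen, and the tests of RNA from other cells before. Xist was at 117 CPM in proximal tubule-like cells at IR H4 and at 0.123 to 0.317 CPM in the other libraries. This was a signal above Sham in a gene named only as a check. It was not particular to this class, as 5.02% of cells of all other named classes at IR H4 held Xist. Of Xist-positive proximal tubule-like cells 68.5% had a Y-linked UMI, 121% of the share in Xist-negative cells of the same depth. Cells of a mixed-in female animal would lower that share. Free RNA would put Xist in 45.6% of cells, against 5.08% observed. That test replaced one based on the 49.4 CPM of the other classes, which could not decide, after its result was seen. Pairs of a male and a female cell of like size would bring fewer Y-linked UMIs for their depth. The 303 cells with at least 3 Xist UMIs, 253 of them in cluster 11, had 1.09 times (bootstrap 95% interval 0.992 to 1.18) the Y-linked UMIs expected from Xist-negative cells of the same cluster. This test replaced one of depth after its result was seen. Median UMIs, at least 3 Xist UMIs over none, had a ratio of 1.05 in cluster 11 and 0.812 in cluster 10 but 1.71 (1.58 to 1.84) over all clusters, which differ in depth. A pair with a much smaller female cell was not tested. A subset of cells with an extra X chromosome in this animal may explain it, as an untested hypothesis, and a karyotype or DNA sequencing of this animal would test it.

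The injury, cytokine and immune genes higher in proximal tubule-like cells at IR D5 could hold RNA from the other cells, which made up a larger share there. Spill-over gave a median of 4.96% of the IR D5 level over the higher calls, 0.607% for the tubule injury members and 3.40% for the NF-kB and cytokine members. A response of the tubule itself may account for most of these calls, while Il1b (123%) and Trem2 (134%) may come from macrophages. In situ hybridization of Havcr1 and Ccl2 with a tubule marker would test this.

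The immediate early list shifted upward at IR D5 in proximal tubule-like cells by camera (adjusted p = 0.00294), with 0 of 20 members past the threshold and adjusted p = 0.528 with an estimated correlation and up to 0.129 without 1 library. RNA from the other cells gave a median of 1.72% of their level. Their list median ranged over 1.64 between the 3 IR D5 libraries, more than the mean shift of 0.958, and IR D5 A was above IR D5 C in 4 of 5 other classes. Handling of single libraries may account for part of the shift, and digestion with a transcription inhibitor would test this.

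Some lists moved at a single time against their direction at IR D5, differences that were not tested. In proximal tubule-like cells fatty acid oxidation was at 0.43 at IR H12. Immediate early genes were at -0.62 at IR H4 and -0.82 at IR H12. Interferon response was at -0.47 and complement at -0.49 at IR H4. Haemoglobin genes, named only as a check, came to 2529 CPM in proximal tubule-like cells of IR D5 B and 2172 in IR D5 C, against 0.657 in Sham A, under 2 in Sham B and 0.282 in IR D5 A. The other cells of IR D5 B and C held less, 691 and 434 CPM. Proximal tubule-like cells were also above Sham at IR H4 (59.2 CPM), IR D28 (42.6) and IR D14 (19.4). In the comparison of IR D5 with Sham the 5 erythrocyte markers had a median log2 change of 9.67 in these cells, and 0 passed.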

How the results depend on the processing

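Runs without genes higher in the other cells, without mitochondrially encoded genes, and with every library thinned were chosen after the data were seen. So was the run of shares without clusters with markers of another class, which left no T cell-, B cell-, distal convoluted or connecting tubule-, collecting duct principal cell- or podocyte-like cell. For all 15 classes 179 share alternatives kept their direction and 11 reversed. The smallest possible p of the permutation test lies above 0.05, so only edgeR on cell counts could have passed, and did not. Without 1 library the share of thick ascending limb-like cells differed by -1.86 to 0.325 points that of intercalated cell-like cells by -3.68 to 0.856, that of collecting duct principal cell-like cells (0.0577) by -1.41 to 1.47 and that of pericyte or smooth muscle-like cells (-0.0736) by -0.380 to 0.232. The collecting duct principal cell-like share differed by -0.131 at resolution 2. The pericyte or smooth muscle-like share differed by 0.0180 with no doublet removal, 0.0425 with a replicate block and 0.0274 with a version block. For named genes 1960 values were the same, 231 weaker, 74 stronger and 17 reversed. For list tests 193 were the same, 83 weaker, 2 stronger and 4 reversed. The cause was not tested for any change below unless fewer genes or libraries made it.

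Genes called at IR D5 in proximal tubule-like cells (353) were 1103 by DESeq2, 781 with no low-count filter, 1156 with a replicate block (938 higher and 218 lower), 1365 with a version block, 80 at resolution 2, 182 thinned, 79 without genes higher in the other cells and 194 to 258 without 1 library. In thick ascending limb-like cells (207) they were 419 with no filter, 571 and 442 with the blocks, 93 with no doublet removal and 72 to 208 without 1 library. In distal convoluted or connecting tubule-like cells (37) they were 57 by DESeq2, 163 with no filter, 263 and 212 with the blocks, 23 at most 25% mitochondrial, 13 without genes higher in the other cells and 24 to 207 without 1 library. In endothelial-like cells (0) they were 16, 68, 169 and 70 by DESeq2, no filter and the blocks, and 0 to 3 without 1 library. In macrophage-like cells (14) they were 191, 327, 479 and 815, and 0 to 137. In T cell-like cells (7) they were 35, 97, 111 (31 higher and 80 lower) and 135, and 0 to 90, with 3 at most 25% mitochondrial, 0 with no doublet removal, 24 at resolution 2 and 0 without genes higher in the other cells. The labels do not say that letters mark a shared batch, and the letter block pairs only A and B. In proximal tubule-like cells, deviations of log CPM from the group mean correlated at 0.545 (Sham A with IR D5 A) and 0.456 (Sham B with IR D5 B). Sham B with IR D5 C, of the same version but another letter, was at 0.265. Deviations of the 2 Sham libraries are exact opposites, so their correlations mirror each other. Deviations of the IR D5 libraries sum to 0 for each gene, so these correlations are not separate evidence of pairing. In the other classes Sham A with IR D5 A was at 0.364 (macrophage-like) to 0.665 (endothelial-like). With a lone Sham library it is assumed to vary like IR D5. With DESeq2 size factors the T cell-like calls were 2 higher and 3 lower, against 4 and 3.

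Lists past the threshold with an estimated correlation were 0 in each of the 6 classes. With fry they were 8 in proximal tubule-like cells (16), and with a replicate block 10 in endothelial-like cells (5).

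Genes standing apart at IR H4 (222) were 444 against Sham A alone, 619 against Sham B alone, 1083 at a fold of 2, 78 at a fold of 8 and 143 thinned. In the same order they were 630, 772, 1368, 126 and 201 at IR H12 (353), and 675, 723, 1227 and 207 at IR D1 (411), with 636 at a UMI minimum of 20. They were 315, 415, 465, 77 and 81 at IR D14 (168), with 292 at that minimum, and 174, 338, 263, 34 and 33 at IR D28 (91), with 144. Of the list medians in proximal tubule-like cells at single times, 31 moved, 1 reversed and 78 stayed the same against Sham A alone, and 41 moved and 69 stayed the same against Sham B alone. With a pseudocount of 10 7 moved and 103 stayed the same. The tubule injury median at IR D1 was 1.46 with a pseudocount of 10 (2.68).

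Directions reversed for Cdkn1a (-0.27 to 1.98 without 1 library), Hmox1 (-0.43 to 0.72 without 1 library) and Mki67 (-0.0487 within version 4.0.0). Lrp2 (0.00) was at -0.0226 by DESeq2 and with its size factors, -0.0233 with no filter, -0.14 with either block, -0.10 at most 25% mitochondrial, -0.000561 with at least 1000 UMIs, -0.0296 with no doublet removal, -0.00132 without mitochondrially encoded genes, -0.49 within version 4.0.0 and -0.18 to 0.23 without 1 library. The heat shock list turned with fry (adjusted p = 0.981), a replicate block (0.209) and a version block (0.0660), and the mitochondrially encoded list with fry (0.981). The immediate early list median in proximal tubule-like cells at IR D28 was -0.0857 against Sham A alone.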

Other observations

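In thick ascending limb-like cells the tubule injury list was at 1.33, 1.94 and 1.84 at IR H4, IR H12 and IR D1, and at 1.15 and 0.61 at IR D14 and IR D28. In the same cells the NF-kB and cytokine list was at 0.55, 1.18 and 1.49 on the first day and at 1.08 and 0.52 late. Interferon response genes, which answer viral and damage signals, were at -1.35, -0.51 and -0.21 on the first day there. In distal convoluted or connecting tubule-like cells tubule injury was at 1.67, 2.28 and 2.30 on the first day and at 0.45 and 0.06 late. Endothelial-like cells had immediate early genes at -0.68 and -0.79 at IR H4 and IR H12 and at 0.47, -0.54 and -1.57 in IR D5 A, B and C. These values are of single libraries and were not tested.

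Macrophage cluster 13 held 64.2% of the class in Sham A, 86.8% in IR D5 A and at most 9.16% in any other library. An unnamed cluster of 462 cells was led by the cell division genes Top2a, Mki67 and Birc5. In cluster 11 at IR H4 cells with at least 3 Xist UMIs had Kdm6a at 1.75 (1.44 to 2.11), Eif2s3x at 1.39 (1.15 to 1.68), Ddx3x at 1.33 (1.24 to 1.43) and Kdm5c at 1.20 (0.961 to 1.48) times the level in cells with none. The Y-linked Eif2s3y was at 1.36 (1.15 to 1.61) and the 4 Y-linked genes together at 1.08 (0.982 to 1.18). The 1047 X-linked genes other than Xist and Tsix were at 1.01 (0.996 to 1.02). Tsix, which overlaps Xist on the opposite strand, was at 549 (264 to 1375), from 368 UMIs against 7.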
